A study of Homo sapiens with 12 samples.

How the data were processed

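RNA of HCT116 cells in 4 groups of 3 biological replicates was prepared with a TruSeq RNA kit, which does not mark the strand, per the labels' protocols. The deposited table held raw read counts, whole numbers per gene symbol and library, with no normalization. Per the submitters' processing notes, the tools were STAR 2.4, SAMtools 1.2 and featureCounts of Subread 1.4.6, with the build GRCh38 (hg38). Neither the labels nor the file states the annotation release, the strand setting or the treatment of reads that map to several places. Columns were matched to samples through the column number given in each sample description. The NF-kB list score was from 5.32 to 5.58 in the TNF-treated libraries and from 3.60 to 3.73 in the others.

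The table held 56634 distinct symbols and 12 columns, with totals from 5835226 to 9281176 counts. Gene positions and types were looked up by symbol in GENCODE 29 (GRCh38), where 36769 symbols were found. Transcript GC content and length were known for 12473 of the 13084 tested genes (95.3%). All 13 mitochondrially encoded protein genes stood at 0 counts in every library, so the mitochondrial share, a usual sign of RNA quality, could not be used. At this depth 1 CPM is about 6 to 9 counts, and a group of 3 libraries at 0 counts allows up to 3 counts over the group.

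Differential expression was tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by group, robust quasi-likelihood dispersions and F-tests. The fit held all 12 libraries with 1 coefficient per group, so that all groups shared an estimate of the spread. Contrasts were TNF against control, Senexin B against control, TNF plus Senexin B against TNF, TNF plus Senexin B against Senexin B, their interaction and the mean TNF effect. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes are Wald errors from the information matrix of the fit, scaled by the posterior quasi-dispersion. They replaced the size of the log2 fold change over the square root of F after the data were seen, since that was too small for large folds over low baselines (0.17 against 0.41 for CXCL8 with TNF). With the mean TNF effect, 1864 genes were called, 1027 higher and 837 lower, of which 99 rose at least 2-fold and 13 fell at least 2-fold. These formed the TNF-induced and TNF-repressed sets. A library's score for a set was the mean log2(CPM + 1), compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 against 3.

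Gene lists were written from textbook knowledge: 27 lists with 746 entries, of which 745 were found after older symbols were matched. They covered NF-kB target genes, chemokine and cytokine genes, NF-kB feedback inhibitors, TNF receptor signalling, immediate early genes, the Mediator kinase module, core Mediator subunits, target genes of Wnt/beta-catenin, p53, TGF-beta and BMP, HIF, Notch and NRF2, interferon-stimulated genes, cholesterol synthesis, the ATF4 and unfolded protein response, heat shock, E2F and S-phase, G2/M, glycolysis, cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, housekeeping genes, epithelial markers, fibroblast markers and blood cell markers. The 25 lists with at least 5 tested members entered limma's camera (3.58.1) at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation. Members were also adjusted over the list alone. Many lists share members.

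Named genes followed a rule. For each of the first 3 comparisons they were the 10 largest fitted increases and the 10 largest decreases among called genes with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the groups. Chance gives such separation in 10% of genes with 3 against 3. For the interaction the rule took 5 and 5, and since no overlap is not defined there, that condition was not applied. Up to 4 called members per list and comparison with the smallest adjusted p were added, along with CDK8, CDK19, CCNC, MED12, MED13, CXCL8, CXCL1, CXCL2, CCL20, NFKBIA, TNFAIP3, ICAM1, IL1A, EGR1, FOS and MYC. IL1A did not pass the filter, with at most 6 counts in a library. Clone-based names and small RNAs were passed over in naming. The low-count genes IKZF3, SERPINA3 and TNFRSF9 are also given for TNF plus Senexin B against Senexin B, outside that rule. Their values there are ratios or bounds from counts.

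Where the reference group held 1 to 3 counts, the ratio of summed counts per library size is given with an exact 95% interval. Where it held 0, the fold is a lower bound against 3 counts over the group.

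The pipeline was tested on simulated counts with 200 genes changed by known folds. For TNF against control it recovered 80.6% of genes changed 1.5-fold, 94.0% at 2-fold and 97.0% at 4-fold, with 8 false calls among 189. For Senexin B against control it recovered 79.1%, 92.5% and 98.5% at these folds, and for TNF plus Senexin B against TNF 79.1%, 91.0% and 97.0%. For TNF plus Senexin B against Senexin B the shares were 79.1%, 92.5% and 95.5%. For the interaction they were 58.2%, 89.6% and 93.9%, with 14 false calls among 175. The simulated genes varied independently, with no GC trend in any library and no changes under 1.5-fold. The median size of the called log2 fold changes was 0.31 for TNF against control. It was 0.27 for Senexin B against control and 0.26 for TNF plus Senexin B against TNF. The simulated rates therefore do not carry over to the calls below.

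The contrasts, gene lists, named-gene rule and most alternatives were chosen before the data were examined: DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a stricter filter of 1 CPM, the replicate number as a term of the model, only the groups compared, each library left out in turn, other sets and pseudocounts for the scores, and the estimated correlation. Added after seeing the data were fits without control replicate 1 and TNF replicate 1, fits without replicate 1 of all groups, offsets corrected for GC content or length by a lowess curve per library, and the alternatives of the count of lists in the interaction. Splits of the libraries were all 10 for each comparison of 3 against 3 and 100 for the interaction and the mean TNF effect, the real one and others drawn at random within strata. No library was left out of the reported values.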

Results

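HCT116, a human colorectal carcinoma cell line, was exposed to TNF-alpha (TNF), to Senexin B, to both or to neither, and polyadenylated RNA was profiled by sequencing. Senexin B inhibits CDK8 and CDK19, the paralogous kinases of the Mediator complex, and TNF is a cytokine that activates the transcription factor NF-kB. The 12 libraries fell into 4 groups of 3 biological replicates. Control cells received 0.1% DMSO for 3 hours. Senexin B cells received the inhibitor at 1 µM for 3 hours. TNF cells received DMSO for 1 hour and then TNF at 10 ng/mL for 2 hours. In the fourth group, TNF plus Senexin B, the inhibitor took the place of DMSO. The series title names the question: what inhibition of the Mediator kinases does to transcription in HCT116 cells with and without TNF.

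The deposited values were read counts for 56634 gene symbols. Total counts were 7315736, 8321910 and 8994809 in control replicates 1, 2 and 3. They were 8479052, 7986987 and 9281176 in Senexin B replicates 1, 2 and 3. They were 5835226, 8262026 and 8305389 in TNF replicates 1, 2 and 3. They were 8401710, 8632701 and 8787674 in TNF plus Senexin B replicates 1, 2 and 3. After a filter on low counts, 13084 genes were tested. The biological coefficient of variation across replicates was 3.62%, so that small differences could pass the test. Between replicates of a group, chi-square per degree of freedom ran from 1.23 (Senexin B replicates 2 and 3) to 2.92 (control replicates 1 and 3). Counting error alone gives about 1. The adjusted p-values cover only the spread among these libraries. Group means below are CPM (counts scaled by TMM-corrected library size) ± SD over 3 libraries. Log2 fold changes of single genes carry their standard errors where first given for a comparison. Counting intervals and floors cover counting error only. TNF replicate 1 had the lowest total and stood apart from its group: across genes, its deviation from TNF replicates 2 and 3 correlated with transcript GC content (Spearman's rho = -0.52, where genes are not independent replicates).

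TNF against control asked which transcripts the cytokine changed within 2 hours. TNF raised chemokines and other NF-kB target genes, some of them, such as CXCL8 and CXCL1, from near 0 counts. CXCL8, a neutrophil chemokine, went from 0.503 ± 0.320 to 76.8 ± 7.57 CPM (n = 3), a 142-fold rise (log2 fold change 7.15 ± 0.41). BIRC3, an inhibitor of apoptosis, went from 3.21 ± 1.31 to 333 ± 38.7 CPM, and CXCL1 from 0.375 ± 0.280 to 23.8 ± 2.80 CPM. TNFAIP3, which encodes the deubiquitinase A20, rose 20.9-fold. Fewer genes fell far: AXIN2, a feedback inhibitor of Wnt signalling, and PTCH1, the Hedgehog receptor, fell by 1.22 ± 0.15 and 1.16 ± 0.17 on the log2 scale.

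By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1309 of 13084 genes differed between TNF and control, 760 higher and 549 lower. At least 2-fold changes were found for 99 of the higher and 21 of the lower genes. All 10 of the genes with the largest fitted increase kept their call in each fit that left out 1 library: CXCL8, BIRC3, CCL20, TNFRSF9, CXCL1, IKZF3, C8orf46, TNFAIP3, SERPINA3 and CXCL2. Of the 10 with the largest fitted decrease, 6 did: ARID5B at -1.55 ± 0.16, RAB3A at -1.25 ± 0.18, AXIN2, DDIT4L at -1.21 ± 0.23, ZNF488 at -1.19 ± 0.19 and PTCH1. Some baselines were too low for a fitted fold to be read as a size. CCL20 had 118 counts with TNF against 1 in control, a ratio of 133 per library size (95% counting interval 23.4 to 5293). The ratio was 28.2 (7.40 to 239) for IKZF3, 24.4 (7.99 to 121) for C8orf46 and 27.03 (4.41 to 1112) for SERPINA3. CXCL8 lies on chromosome 4 from 73740506 to 73743716 and BIRC3 on chromosome 11 from 102317450 to 102339403 (GENCODE 29, GRCh38). CXCL1, CXCL2 and CXCL3 are closely related genes, and reads shared between them could have been split or dropped in counting.

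**Figure D1:**
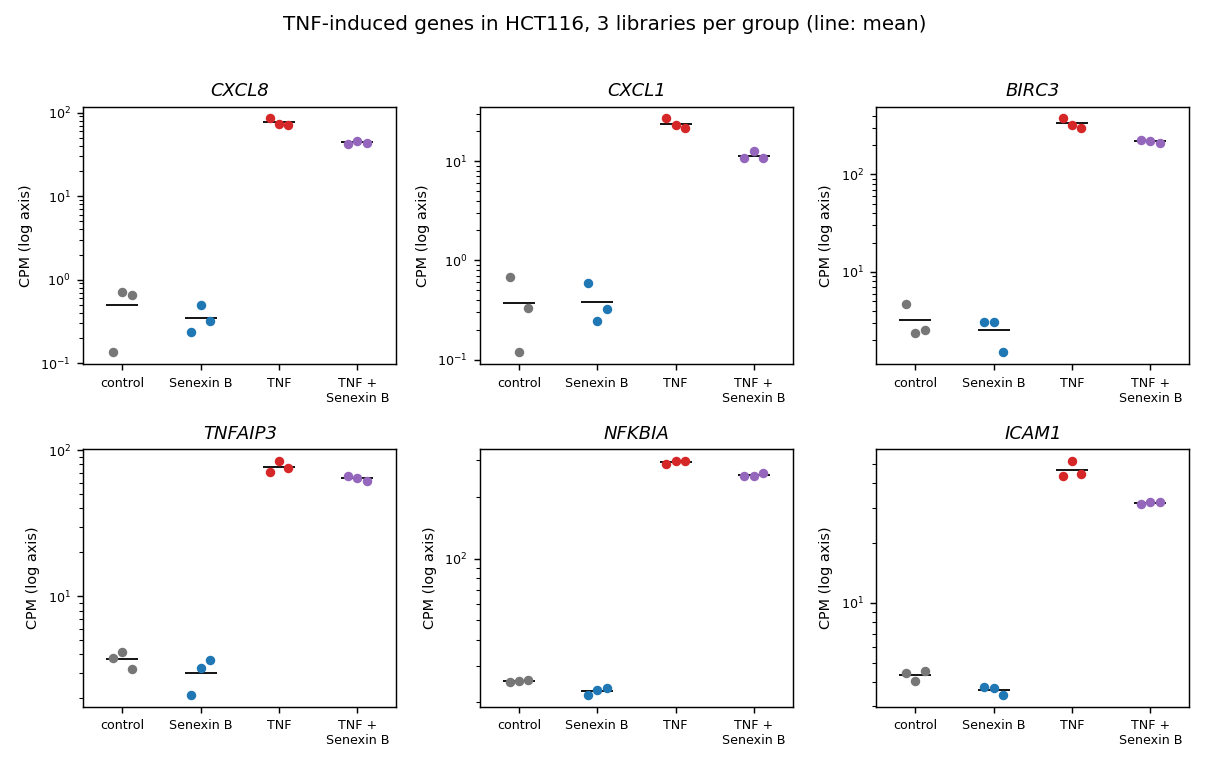
CPM of 6 TNF-induced genes in each of the 12 libraries, on log axes that differ between panels, with 3 points and a line at the mean per group. CXCL8 averaged 0.503 CPM in control, 76.8 CPM with TNF and 44.0 CPM with TNF plus Senexin B.

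NF-kB target genes rose together with TNF. Of 43 tested members, 39 rose, 0 fell and 4 did not pass, and 41 rose when adjusted over the list alone (camera adjusted p = 5.31e-07 with an estimated correlation). Examples are NFKBIA, which encodes the NF-kB inhibitor IkB-alpha, at 3.54 ± 0.06 (25.3 ± 0.237 to 294.5 ± 4.63 CPM), the adhesion molecule ICAM1 at 3.43 ± 0.15, TNFAIP2 at 3.29 ± 0.05 and NFKB2 at 2.10 ± 0.05. Of 13 chemokine and cytokine genes, 11 rose and 2 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 1.04e-59). CSF1, a macrophage growth factor, stood at 2.90 ± 0.17, and the growth factor EREG at 0.66 ± 0.04. Among NF-kB feedback inhibitors, 11 of 14 rose and 0 fell, again 11 when adjusted over the list alone (camera adjusted p = 8.28e-71), including BCL3 at 2.04 ± 0.12 and NFKBIE at 1.56 ± 0.09. Of 24 genes of TNF receptor signalling, 8 rose, 1 fell and 15 did not pass, with 9 and 1 adjusted over the list alone (camera adjusted p = 2.23e-12). Those lists share members with the NF-kB list, so they are not separate evidence. Estimated correlations gave them larger camera adjusted p: 2.45e-06 for chemokine and cytokine genes and for feedback inhibitors, and 0.000247 for TNF receptor signalling.

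Interferon-stimulated genes, ATF4 and unfolded protein response genes and p53 target genes also rose as lists. With an estimated correlation the camera adjusted p was 0.000243, 0.00777 and 0.00733 in that order, and 0.00733 for immediate early genes. Of 37 interferon-stimulated genes, 15 rose and 0 fell, with 18 and 1 adjusted over the list alone (camera adjusted p = 1.36e-11). IRF1, a transcription factor of the interferon response, rose by 2.27 ± 0.09 on the log2 scale, DDX58, which encodes the RNA sensor RIG-I, by 1.34 ± 0.11, and the peptide transporter TAP1 by 0.82 ± 0.07. Of 45 immediate early genes, 20 rose, 7 fell and 18 did not pass, with 21 and 9 adjusted over the list alone (camera adjusted p = 1.32e-15). JUN rose from 28.0 ± 1.41 to 69.8 ± 3.39 CPM and MAFF by 1.47 ± 0.08, whereas FOS was at -0.71 ± 0.20 and was no longer called without control replicate 3 (edgeR adjusted p = 0.0815). EGR1 was at -0.17 ± 0.08 (edgeR adjusted p = 0.239). Of 25 genes of the ATF4 and unfolded protein response, 10 rose and 1 fell, with 12 and 2 adjusted over the list alone (camera adjusted p = 1.63e-06). They included ATF3 at 1.46 ± 0.09 and STC2, a stress-induced secreted glycoprotein, at 0.86 ± 0.05. Of 30 p53 target genes, 7 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 0.000218), with the death receptor TNFRSF10B at 0.80 ± 0.04 and the pro-apoptotic BBC3 at 1.06 ± 0.12. Of 19 heat shock genes, 2 rose and 4 fell, with 4 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.743, test down, median 0.01, mean -0.03), with HSPA1B at -0.36 ± 0.05.

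Lists for developmental signalling went down with TNF under the preset correlation only. Of 20 Wnt/beta-catenin target genes, 3 rose and 6 fell, with 4 and 8 adjusted over the list alone (camera adjusted p = 0.0119, and adjusted p = 0.105 with an estimated correlation). RNF43, an inhibitor of Wnt receptors, fell by 0.62 ± 0.07, and MYC was higher by 0.43 ± 0.04. Of 18 TGF-beta and BMP target genes, 3 rose and 5 fell, with 3 and 6 adjusted over the list alone (camera adjusted p = 0.00925, and adjusted p = 0.102 with an estimated correlation). BMP4 went from 175.5 ± 3.05 to 88.2 ± 3.25 CPM, and ID2 and ID1, inhibitors of differentiation, fell by 1.13 ± 0.08 and 0.93 ± 0.06. Of 10 Notch target genes, 1 rose and 3 fell, with 1 and 6 adjusted over the list alone (camera adjusted p = 0.0336, and adjusted p = 0.177 with an estimated correlation). The Notch call was lost without control replicate 1 (adjusted p = 0.0713), TNF replicate 1 (0.122) or control replicate 3 (0.0578), and with GC-corrected offsets (0.556). HES1 fell by 0.72 ± 0.14.

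Gene-wise changes with TNF leaned on GC content. Across genes, Spearman's rho between the log2 fold change and transcript GC was -0.41, and -0.28 without the 2 libraries that stood apart from their groups, control replicate 1 and TNF replicate 1. The median GC content was 43.3% for the higher genes, 59.5% for the lower genes and 48.4% for all genes. Without both libraries 937 genes were called, 602 higher and 335 lower, 807 of them among the 1309. With GC-corrected offsets 1040 were called, 697 higher and 343 lower, 815 of them among the 1309. The named genes CXCL8, BIRC3, CXCL1, TNFAIP3, NFKBIA, ICAM1, AXIN2, BMP4 and ID1 kept their calls in both. In TNF plus Senexin B against Senexin B, which compares neither library, Spearman's rho was -0.185. There the median GC content was 47.65% for the higher and 55.89% for the lower genes, so the trend was not confined to those libraries. The offsets are fitted per library and would also remove a GC trend caused by TNF.

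Senexin B against control asked what kinase inhibition did without cytokine. The inhibitor lowered the transcription factor genes EGR1 and JUN and several heat shock genes. EGR1, a zinc finger factor induced by growth signals, went from 96.8 ± 9.86 to 35.6 ± 1.32 CPM (n = 3), a log2 fold change of -1.45 ± 0.10. JUN went from 28.0 ± 1.41 to 11.2 ± 1.03 CPM, and the chaperone gene HSPA1B from 153 ± 7.74 to 83.5 ± 1.74 CPM. CDKN1A, which encodes the cell cycle inhibitor p21, went from 152 ± 2.92 to 89.5 ± 0.698 CPM. Among higher genes, MYC went from 412 ± 16.8 to 563 ± 6.98 CPM and TRIB3, a pseudokinase induced by ATF4, from 67.9 ± 3.58 to 98.7 ± 2.17 CPM.

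By edgeR's quasi-likelihood test, 398 genes differed between Senexin B and control, 200 higher and 198 lower, of which 2 and 7 changed at least 2-fold. Of the 10 genes with the largest fitted decrease, 7 kept their call in each fit that left out 1 library: EGR1, JUN, CSRNP1 at -1.18 ± 0.12, the vascular transcription factor KLF2 at -1.06 ± 0.13, FOS at -1.04 ± 0.21, HSPA1B and SERTAD1 at -0.78 ± 0.10. Of the 10 with the largest fitted increase, 6 did: LURAP1L at 1.49 ± 0.34, the nuclear receptor NR4A2 at 0.63 ± 0.12, CHAC1 at 0.61 ± 0.11, MYEOV at 0.60 ± 0.05, the keratin KRT80 at 0.59 ± 0.08 and the insulin signalling adaptor IRS2 at 0.58 ± 0.10. EGR1 lies on chromosome 5 from 138465490 to 138469315, JUN on chromosome 1 from 58780788 to 58784327 and MYC on chromosome 8 from 127735434 to 127741434 (GENCODE 29, GRCh38). Reads of HSPA1B may be shared with its near-identical copy HSPA1A, so their separate values are uncertain. The count of 398 was 261, 250 and 236 without Senexin B replicates 1, 2 and 3 in turn, and 416 without control replicate 1 and TNF replicate 1 (327 shared). With GC-corrected offsets it was 591, with 393 shared.

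**Figure D2:**
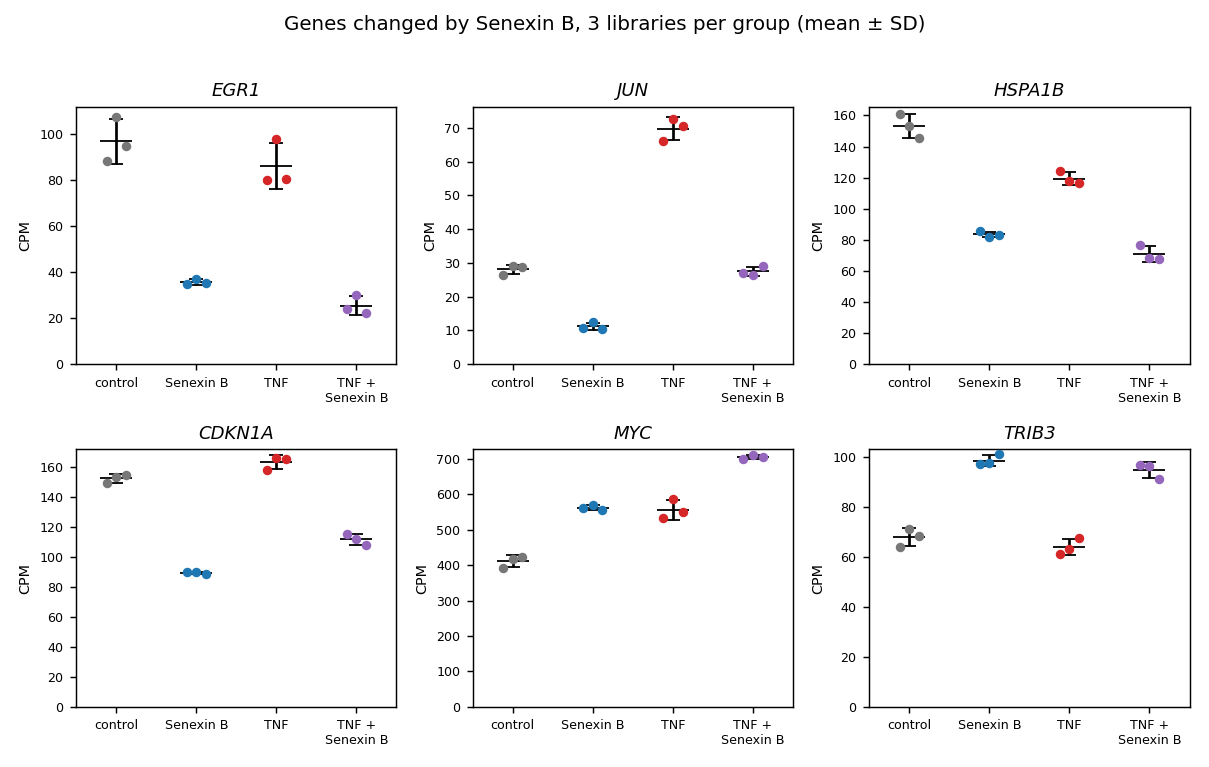
CPM of 6 genes changed by Senexin B, on linear axes from 0, with 3 points per group and bars for the mean and SD. In the groups without TNF, EGR1 averaged 96.8 CPM in control and 35.6 CPM with Senexin B, and MYC averaged 412 and 563 CPM.

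Heat shock genes fell together with Senexin B: of 19 tested members, 7 fell, 0 rose and 12 did not pass, and 10 fell when adjusted over the list alone (camera adjusted p = 1.16e-18). The co-chaperones DNAJB1 and DNAJA1 stood at -0.63 ± 0.04 and -0.35 ± 0.04, and HSPA8, the constitutive HSC70, at -0.37 ± 0.03. Genes of the ATF4 and unfolded protein response rose: 11 of 25, with 0 lower and 12 higher adjusted over the list alone (camera adjusted p = 3.29e-15). SESN2 was at 0.55 ± 0.08, TRIB3 at 0.54 ± 0.06, STC2 at 0.43 ± 0.05 and XBP1 at 0.38 ± 0.06. Of 20 Wnt/beta-catenin target genes, 6 rose and 0 fell, with 6 and 1 adjusted over the list alone (camera adjusted p = 7.95e-07). They included JAG1, a Notch ligand, at 0.38 ± 0.06, RNF43 at 0.32 ± 0.06 and MYC at 0.45 ± 0.04. Of 18 TGF-beta and BMP target genes, 4 rose and 1 fell, with 5 and 1 adjusted over the list alone (camera adjusted p = 1.05e-05), among them ID3 at 0.52 ± 0.08, ID1 at 0.46 ± 0.05 and BMP4 at 0.27 ± 0.04. Of 25 cholesterol synthesis genes, 7 rose and 0 fell, with 8 and 0 adjusted over the list alone (camera adjusted p = 2.84e-05), with MSMO1 at 0.38 ± 0.05 and SQLE at 0.23 ± 0.05. The calls of these 5 lists held with an estimated correlation. There the camera adjusted p was 0.00694 for heat shock, 0.00218 for the ATF4 and unfolded protein response and 0.0128 for Wnt/beta-catenin. It was 0.0157 for the TGF-beta and BMP list and 0.0157 for cholesterol synthesis.

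For 4 other lists the call with Senexin B was lost with an estimated correlation. Of 45 immediate early genes, 8 rose and 10 fell, with 10 and 15 adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.353 with an estimated correlation). The kinase-regulating gene TRIB1 rose by 0.33 ± 0.04 while EGR1 and JUN fell. That call was also lost without control replicate 2 (adjusted p = 0.0672) or Senexin B replicate 3 (0.163). Of 30 p53 target genes, 2 rose and 3 fell, with 2 and 4 adjusted over the list alone (camera adjusted p = 0.0375, and adjusted p = 0.0958 with an estimated correlation), and the call was lost without control replicate 2 (0.111), Senexin B replicate 2 (0.157) or Senexin B replicate 3 (0.0566). CDKN1A was at -0.77 ± 0.05 and MDM2, which encodes the ubiquitin ligase of p53, at -0.23 ± 0.04, while SESN2 and the polo-like kinase PLK2 were higher. Of 43 NF-kB target genes, 3 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.165 with an estimated correlation), with IER3 at -0.33 ± 0.05. Of 59 cytosolic ribosomal protein genes, 0 passed over all genes or adjusted over the list alone, at a median of 0.03 (camera adjusted p = 0.0209, and adjusted p = 0.661 with an estimated correlation). That last direction turned without Senexin B replicate 1 (adjusted p = 0.964), and the call was lost without control replicate 2 (0.1999).

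Transcripts of the drug's targets, CDK8 and CDK19, gave no call. With Senexin B, CDK8 was at 0.06 ± 0.07 (edgeR adjusted p = 0.797), CDK19 at -0.08 ± 0.09 (0.775), cyclin C gene CCNC at -0.07 ± 0.06 (0.668) and MED12 at -0.15 ± 0.09 (0.467). These 4 genes passed in none of the comparisons by edgeR's test. MED13 was at -0.16 ± 0.04 (edgeR adjusted p = 0.0286) and was not called without control replicate 1, Senexin B replicate 1 or Senexin B replicate 2, with a largest adjusted p of 0.282.

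TNF plus Senexin B against TNF asked what the inhibitor did to cells that also received the cytokine. CXCL8, CXCL1 and CXCL2, chemokine genes induced by TNF, were lower. CXCL8 averaged 44.0 ± 2.02 CPM against 76.8 ± 7.57 with TNF alone (log2 fold change -0.79 ± 0.07, n = 3), CXCL1 11.3 ± 1.08 against 23.8 ± 2.80 CPM, and CXCL2 1.72 ± 0.377 against 4.20 ± 0.370 CPM. EGR1 and JUN were lower again, at -1.77 ± 0.11 and -1.35 ± 0.08 on the log2 scale. Not every TNF-induced gene was lower: CCL20, a chemokine for dendritic cells and lymphocytes, averaged 5.57 ± 0.268 CPM against 5.36 ± 0.212 (log2 fold change 0.06 ± 0.19, edgeR adjusted p = 0.906).

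By edgeR's quasi-likelihood test, 713 genes differed between TNF plus Senexin B and TNF, 380 higher and 333 lower, of which 5 and 9 changed at least 2-fold. Of the 10 with the largest fitted decrease, 6 kept their call in each fit that left out 1 library: EGR1, JUN, CSRNP1 at -1.32 ± 0.13, CXCL2 at -1.26 ± 0.29, KLF2 at -1.26 ± 0.17 and CXCL1 at -1.05 ± 0.12. Of the 10 with the largest fitted increase, 5 did: LURAP1L at 1.12 ± 0.22, FRAT2, an activator of Wnt signalling, at 0.84 ± 0.19, the splicing factor gene PRPF40B at 0.81 ± 0.18, BORCS8 at 0.74 ± 0.17 and NR4A2 at 0.73 ± 0.13. The count of 713 was 463 without TNF replicate 1, and 461, 468 and 451 without TNF plus Senexin B replicates 1, 2 and 3 in turn. Without control replicate 1 and TNF replicate 1 together it was 555 (468 shared), and with GC-corrected offsets 609 (447 shared). Across genes, Spearman's rho between this log2 fold change and transcript GC was 0.37, and 0.18 without both libraries. The median GC content was 56.6% for the higher and 41.4% for the lower genes.

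NF-kB target genes were lower with the inhibitor than with TNF alone: of 43, 15 fell, 3 rose and 25 did not pass, with 17 and 3 adjusted over the list alone (camera adjusted p = 6.04e-15). NFKBIZ, a nuclear co-regulator of NF-kB, was at -0.71 ± 0.14, the proteoglycan SDC4 at -0.42 ± 0.04, the surface protein CD83 at -0.60 ± 0.06, ICAM1 at -0.55 ± 0.08 and NFKBIA at -0.21 ± 0.04. TNFAIP3 was at -0.26 ± 0.07 and was not called without TNF replicate 2 (edgeR adjusted p = 0.115) or TNF plus Senexin B replicate 3 (0.0754). Of 13 chemokine and cytokine genes, 3 fell (CXCL8, CXCL1 and CXCL2) and 3 rose, with 4 and 4 adjusted over the list alone (camera adjusted p = 0.00579, and adjusted p = 0.0522 with an estimated correlation). The angiogenic factor VEGFA was higher by 0.37 ± 0.08. Of 14 NF-kB feedback inhibitors, 4 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.0545 with an estimated correlation), with the deubiquitinase CYLD at -0.41 ± 0.09. In the presence of the inhibitor, CXCL8 was 121-fold, CXCL1 28.4-fold, NFKBIA 11.2-fold and SDC4 3.69-fold higher in TNF plus Senexin B than in Senexin B.

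The set of 99 genes raised at least 2-fold by TNF, averaged over cells with and without Senexin B, moved little as a whole. Its score, the mean log2(CPM + 1) per library, was 2.86 ± 0.003 in control, 2.81 ± 0.03 with Senexin B, 4.42 ± 0.03 with TNF and 4.38 ± 0.02 with both (SD, n = 3). TNF plus Senexin B minus TNF was -0.04 ± 0.02 (exact two-sided permutation p = 0.2, n = 3 per group), and Senexin B minus control was -0.05 ± 0.01 (exact p = 0.1, the smallest that 3 against 3 allows) and -0.02 without control replicate 2. Within the set, 16 genes were lower and 12 higher in TNF plus Senexin B than in TNF. JUN, CXCL2, CXCL1 and CXCL8 led the lower genes. LURAP1L led the higher genes. Without TNF, Senexin B also lowered JUN (-1.33 ± 0.11) and raised LURAP1L (1.49), while CXCL2, CXCL1 and CXCL8, near 0 counts there, gave no call. In the interaction only 1 gene of the set passed, SDC4. Of the 28 genes raised at least 4-fold, 13 were lower and 3 higher, and that score differed by -0.20 ± 0.03 (exact permutation p = 0.1). The set was chosen on these libraries by the mean TNF effect, which is orthogonal to the Senexin B contrasts.

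Heat shock genes were lower in TNF-treated cells as well: 8 of 19 fell and 0 rose, with 11 lower adjusted over the list alone (camera adjusted p = 4.35e-15), with HSPA1B at -0.75 ± 0.06, DNAJB1 at -0.59 ± 0.04 and HSPA8 at -0.36 ± 0.03. Of 20 Wnt/beta-catenin target genes, 7 rose and 0 fell, with 8 and 2 adjusted over the list alone (camera adjusted p = 3.81e-10), including JAG1 at 0.62 ± 0.05, RNF43 at 0.57 ± 0.07 and MYC at 0.34 ± 0.04. Of 18 TGF-beta and BMP target genes, 6 rose and 2 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 8.35e-06). ID1 was at 0.67 ± 0.06 and BMP4 at 0.58 ± 0.05, while KLF10, a TGF-beta-inducible repressor, was at -0.32 ± 0.05. Of 25 cholesterol synthesis genes, 7 rose and 0 fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.000171), with SQLE at 0.28 ± 0.05 and DHCR7 at 0.28 ± 0.05. Of 25 ATF4 and unfolded protein response genes, 5 rose and 1 fell, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.000272), led by TRIB3 at 0.57 ± 0.06 and XBP1 at 0.41 ± 0.06. Of 30 p53 target genes, 3 fell and 1 rose, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.00602), with CDKN1A at -0.55 ± 0.05 and MDM2 at -0.29 ± 0.04. The calls in this paragraph and that of the NF-kB list held with an estimated correlation. Their camera adjusted p was then 0.00521 for the NF-kB and Wnt/beta-catenin lists, 0.00733 for heat shock and 0.0218 for TGF-beta and BMP. It was 0.0329 for cholesterol synthesis and for the ATF4 list, and 0.0343 for p53 target genes.

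Immediate early genes moved both ways in this comparison and were not called as a list. Of 45, 9 rose and 9 fell, with 12 and 13 adjusted over the list alone (camera adjusted p = 0.263, test down, median 0.02, mean -0.07). SRF, the serum response factor gene, was at 0.54 ± 0.05 and TRIB1 at 0.43 ± 0.04, against the falls of EGR1 and JUN.

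Lists of proliferation genes were slightly lower with both agents than with TNF alone, under the preset correlation only. Of 33 E2F and S-phase genes, 7 fell and 0 rose, with 8 and 0 adjusted over the list alone (camera adjusted p = 0.000828, and adjusted p = 0.0545 with an estimated correlation). CCNE2, which encodes cyclin E2, was at -0.60 ± 0.09, and RRM2, a subunit of ribonucleotide reductase, at -0.39 ± 0.04. Of 30 G2/M genes, 5 fell and 0 rose, with 9 and 0 adjusted over the list alone (camera adjusted p = 0.000521, and adjusted p = 0.0783 with an estimated correlation), with CKS2 at -0.35 ± 0.05. Of 37 interferon-stimulated genes, 3 fell and 0 rose, with 7 and 0 adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.0545 with an estimated correlation). IRF1 was at -0.30 ± 0.06. The interferon call was lost without TNF plus Senexin B replicate 2 (adjusted p = 0.0774) or TNF replicate 3 (0.0557).

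**Figure D3:**
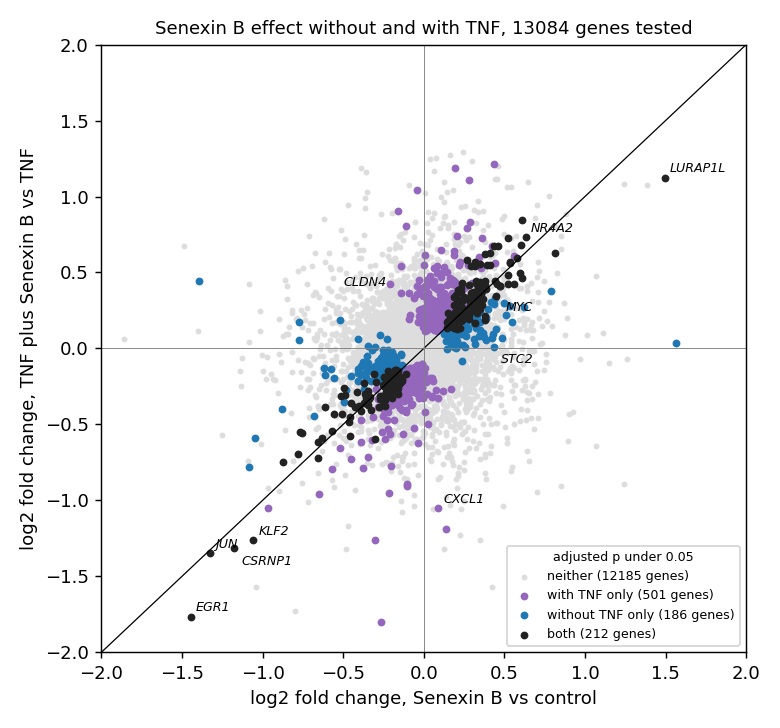
Log2 fold change of Senexin B against control (x axis) and of TNF plus Senexin B against TNF (y axis) for the tested genes, with 2 genes outside the axes and the diagonal drawn. The 212 genes called in both comparisons share their direction, while 186 were called without TNF only and 501 with TNF only, which is no test of a difference.

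TNF plus Senexin B against Senexin B gave the TNF response in the presence of the inhibitor. TNF raised the NF-kB targets here too: CXCL8 by 6.92 ± 0.50 on the log2 scale (0.350 ± 0.133 to 44.0 ± 2.02 CPM, n = 3), NFKBIA by 3.48 ± 0.06, TNFAIP2 by 3.22 ± 0.05 and TNFAIP3 by 4.42 ± 0.17. CCL20 and TNFRSF9 had 0 counts in all Senexin B libraries and were at least 48.2-fold and at least 83.5-fold higher, against a floor of 3 counts over the group. IKZF3 and SERPINA3 had ratios of 32.6 (95% counting interval 8.66 to 275) and 20.03 (6.53 to 99.9). ID2 and AXIN2 fell by 1.14 ± 0.08 and 1.01 ± 0.15.

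By edgeR's quasi-likelihood test, 779 genes differed between TNF plus Senexin B and Senexin B, 559 higher and 220 lower, of which 99 and 12 changed at least 2-fold. This comparison shares no library with TNF against control, and the calls of both shared 409 higher genes (32.5 if the lists were independent) and 126 lower genes (9.23 if independent), with 0 of opposite direction. Likewise the Senexin B comparisons with and without TNF share no library. Their calls had 123 higher genes (5.81 if independent) and 89 lower genes (5.04 if independent) in common, with 0 of opposite direction. Without control replicate 1 and TNF replicate 1, 1036 genes were called, including all 779, and with GC-corrected offsets 888, including 741. With only the groups compared, 978 genes were called here and 881 for TNF against control, the reverse of the order in the main fit. The counts are therefore no measure of the size of the TNF response.

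Of 43 NF-kB target genes, 38 rose and 0 fell, with 39 and 0 adjusted over the list alone (camera adjusted p = 2.60e-08 with an estimated correlation), at a median of 1.68, which was the same with CCL20 and TNFRSF9 set at their bounds. Of 13 chemokine and cytokine genes, 12 rose, also when adjusted over the list alone (camera adjusted p = 9.86e-53), with LIF, a cytokine of the interleukin 6 family, at 0.79 ± 0.06. Of 14 feedback inhibitors, 10 rose, also when adjusted over the list alone (camera adjusted p = 2.44e-78), and BCL3 was at 2.38 ± 0.12. Of 24 genes of TNF receptor signalling, 6 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 8.91e-15), with BIRC2 at 1.60 ± 0.06. Of 45 immediate early genes, 23 rose and 5 fell, with 24 and 5 adjusted over the list alone (camera adjusted p = 8.71e-22), with ZFP36, an mRNA decay factor, at 1.43 ± 0.09. Of 37 interferon-stimulated genes, 13 rose and 0 fell, with 14 and 0 adjusted over the list alone (camera adjusted p = 5.35e-11), with the RNA sensor gene IFIH1 at 1.66 ± 0.14. Of 30 p53 target genes, 7 rose and 0 fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.000454), with PLK2 at 0.83 ± 0.04. Estimated correlations gave a camera adjusted p of 7.06e-06 for chemokine and cytokine genes, 4.71e-07 for feedback inhibitors and 0.000133 for TNF receptor signalling. They gave 0.00232 for immediate early genes, 0.000239 for interferon-stimulated genes and 0.00915 for p53 target genes. Of 18 TGF-beta and BMP target genes, 3 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.1 with an estimated correlation). Of 25 ATF4 and unfolded protein response genes, 7 rose and 0 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.00283, and adjusted p = 0.0677 with an estimated correlation), with ATF3 at 1.18 ± 0.08.

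The interaction tested whether the effect of Senexin B differed with and without TNF. CLDN4, a tight junction claudin, averaged 106 ± 6.82 CPM with Senexin B against 117 ± 1.13 in control, and 149 ± 2.15 CPM with both agents against 116 ± 2.68 with TNF (interaction log2 fold change 0.50 ± 0.07, n = 3). STC2 went from 109 ± 5.70 to 147 ± 3.67 CPM with Senexin B alone, and stood at 199 ± 3.39 with both agents and 197 ± 8.14 CPM with TNF (interaction -0.42 ± 0.07). SDC4, a heparan sulfate proteoglycan, was the only NF-kB target gene of the list past the threshold, at -0.31 ± 0.06. That call was lost without control replicate 2, Senexin B replicates 2 or 3, or TNF plus Senexin B replicates 1 or 3 (largest adjusted p = 0.205). ASNS, which encodes asparagine synthetase, was at -0.32 ± 0.06, and its call was lost without control replicate 1, any Senexin B library, or TNF plus Senexin B replicates 1 or 3 (0.143). The transcriptional regulator gene IRF2BPL was at 0.45 ± 0.09 and kept its call only without control replicate 3, Senexin B replicate 1 or TNF replicates 2 or 3 (0.449). BMP4 was at 0.32 ± 0.07 and kept its call only without TNF replicate 1 (0.348).

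Those 6 genes were all that passed by edgeR's quasi-likelihood test, 3 higher and 3 lower, while 796 had an unadjusted p under 0.05 and DESeq2 called 4. Leaving out 1 library left 2 to 9 calls: 3 without control replicate 1 or control replicate 2, and 2 without Senexin B replicate 2 or 3 or TNF plus Senexin B replicate 1 or 3. CLDN4 and STC2 were called in all 12 of these fits. The chemokines were not past the threshold: the interaction was -1.14 ± 0.69 for CXCL1 (edgeR adjusted p = 0.834), -0.96 ± 0.96 for CXCL2 (0.902) and -0.22 ± 0.65 for CXCL8 (0.978), where the baselines without TNF were too near 0 to set a narrow error. Of 43 NF-kB target genes, 1 was lower and 0 higher in the interaction, also when adjusted over the list alone. That list was not called (camera adjusted p = 0.436, and 0.78 with an estimated correlation, test down, median -0.04, mean 0.02). Its score gave an interaction of -0.11 ± 0.03 (SE), for which no p-value was computed. The score is the mean log2(CPM + 1), which compresses changes of members near 0 counts without TNF, such as CXCL8. An equal fold drop with and without TNF would therefore give a negative value, so the score does not decide the question. The fitted mean also takes in folds over such low baselines. Of 25 ATF4 and unfolded protein response genes, 2 were lower and 0 higher in the interaction, with 4 and 0 adjusted over the list alone (camera adjusted p = 0.00576, and adjusted p = 0.319 with an estimated correlation). Of 13 epithelial markers, only CLDN4 passed, also when adjusted over the list alone (camera adjusted p = 0.00952, and adjusted p = 0.516 with an estimated correlation). The epithelial call was lost without TNF replicate 1, Senexin B replicate 2, control replicate 3, TNF replicate 3 or TNF plus Senexin B replicate 3, with a largest adjusted p of 0.0966, and with GC-corrected offsets (0.0741).

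**Figure D4:**
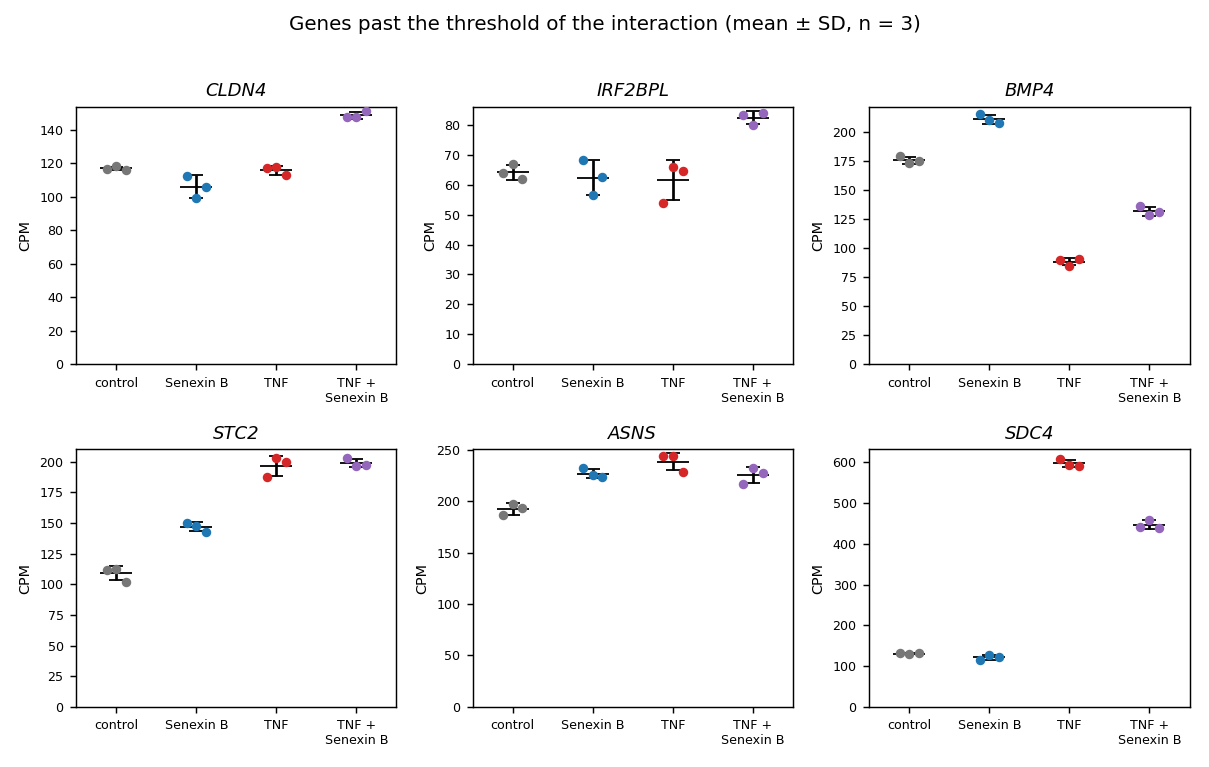
CPM of the 6 genes past the threshold of the interaction, on linear axes from 0, with 3 points per group and bars for the mean and SD. CLDN4 averaged 117, 106, 116 and 149 CPM in control, Senexin B, TNF, and TNF plus Senexin B, and STC2 averaged 109, 147, 197 and 199 CPM.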

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

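The effect of Senexin B differed with and without TNF for 6 genes by edgeR's interaction test, and each is given with its largest adjusted p in the 12 fits that leave out 1 library. CLDN4 had an interaction log2 fold change of 0.50 (adjusted p = 4.41e-05, largest 0.00208) and STC2 one of -0.42 (0.000375, largest 0.0145), and both kept their call in all 12. SDC4 was at -0.31 (adjusted p = 0.0117) and was called in 7 of the fits (largest 0.205). ASNS was at -0.32 (0.0117) and was called in 6 (largest 0.143), IRF2BPL at 0.45 (0.0316) in 4 (largest 0.449) and BMP4 at 0.32 (0.0446) in 1 (largest 0.348). DESeq2 gave adjusted p = 0.068 for BMP4 and 0.112 for IRF2BPL, so neither passed there, and IRF2BPL had 0.0892 without control replicate 1 and TNF replicate 1. By edgeR's test all 6 passed with GC-corrected offsets (largest adjusted p = 0.0265, IRF2BPL) and with a replicate block (largest 0.0244).

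The patterns below were picked after seeing the data, and the bounds of each test were written before the test was run.

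TNF replicate 1 stood apart from TNF replicates 2 and 3, and GC content may account for it. Across genes, its deviation correlated with transcript GC at Spearman's rho = -0.52, against -0.16 to 0.36 in the other libraries, where replicates 2 and 3 are themselves measured against replicate 1. Transcript length gave rho = 0.0903, inside the bound set for no effect. Thinned to equal totals of 5835226 counts, its mean correlation with its group was 0.990, still the lowest, so depth alone does not account for it. Whether the GC trend arose in library preparation or in the cells could not be told from 1 library.

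More genes passed for Senexin B with TNF (713) than without (398), a ratio of 1.79. Without control replicate 1 and TNF replicate 1 the ratio was 1.33, between the bounds set for those libraries as the cause and for no part of theirs. Other fits brought the counts close or turned their order. With GC-corrected offsets 609 genes passed with TNF and 591 without, and with only the groups compared 544 and 511. Without TNF replicate 1 alone, 463 passed with TNF and 589 without, in a fit that held fewer TNF libraries. Over 1318 genes called for the mean Senexin B effect, the signed score difference was 0.241 ± 0.02 with TNF and 0.207 ± 0.01 without (SE, n = 3 per group), a ratio of 1.17, also between its bounds. A larger effect in the presence of TNF could therefore be neither shown nor ruled out, and the ratio of counts is no measure of it.

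The interaction calls held 2 genes of the ATF4 and unfolded protein response list, STC2 and ASNS, and a weaker response of that list to Senexin B in the presence of TNF might lie behind them. The list as a whole had a camera adjusted p = 0.00576, which met the bound, but 0.319 with an estimated correlation and 0.173 without its called members, and 16 members were negative and 9 positive. For a single library deciding the calls the bounds conflicted. The largest unadjusted p of any call in any fit was 0.000238, which met the bound against it, yet only 2 of 6 calls kept an adjusted p under 0.1 in every fit, which met the bound for it. The evidence is in line with a difference for STC2 and leaves the list open.

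Other splits of the same libraries were run as a check of each count. For each comparison of 3 against 3 there were 10 splits, too few splits for a share under 0.05. Other splits mix treated and untreated libraries in a group, so the treatment effect enters their spread and keeps their counts low. The highest other counts are therefore no measure of what chance alone would give. The real value and the highest other were 1309 and 0 for TNF against control, 398 and 1 for Senexin B against control, 713 and 0 for TNF plus Senexin B against TNF, and 779 and 0 for TNF plus Senexin B against Senexin B, so that 1 split of 10, the real one, reached each count. For the mean TNF effect, 1 of 100 splits reached 1864, the real one, and the highest other was 172. For the interaction, 9 of 100 splits reached 6 genes, a share over 0.05, and the highest other was 143. Looked at afterwards, the 8 besides the real one came from 10 splits whose contrast held more than 1 Senexin B effect, and the other 89 gave at most 3. Since those 10 splits hold the drug effect itself, the share neither shows nor excludes a chance origin of the 6 calls.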

How the results depend on the processing

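Of 263 alternative values of the counts and scores, 230 stayed the same and 33 moved (counts by over 1.5 times, scores by over the pooled SD of the libraries). Only the scores could reverse by these labels, and 0 did. For those that moved, the cause was not tested, beyond that fits without a library hold fewer samples. For 348 pairs of a named gene and a comparison, 5853 alternatives gave 5420 same, 423 weaker, 10 stronger and 0 reversed calls. DESeq2's Wald test called 850 genes for TNF against control (849 shared) and 475 for TNF plus Senexin B against TNF (474 shared), and 10 genes passed the interaction without a filter. DESeq2 called 4 for the interaction, with 381 at an unadjusted p under 0.05.

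Leaving out 1 library gave 876 to 1348 genes for TNF against control. Of these, 324 (without control replicate 3) to 617 (without TNF replicate 2) were lower. It gave 583 to 916 for TNF plus Senexin B against Senexin B. Of these, 131 (without TNF plus Senexin B replicate 3) to 287 (without TNF replicate 1) were lower. It gave 236 (without Senexin B replicate 3) to 589 (without TNF replicate 1) for Senexin B against control. It gave 451 (without TNF plus Senexin B replicate 3) to 815 (without TNF replicate 2) for TNF plus Senexin B against TNF. For the interaction it gave 2 (without TNF plus Senexin B replicate 1) to 9 (without TNF replicate 2), and for the mean TNF effect 1513 to 1965.

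The score difference of the TNF-induced set, TNF plus Senexin B minus TNF, was -0.20 with the 4-fold set, -0.21 with the NF-kB list and -0.076 without replicate 1 of all groups. It ran from -0.063 to -0.038 when 1 library was left out. Senexin B minus control was -0.11 with the 4-fold set and -0.097 with the NF-kB list, and ran from -0.058 without Senexin B replicate 3 to -0.021 without control replicate 2.

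With an estimated correlation, camera called 5 lists for Senexin B against control, 7 for TNF plus Senexin B against TNF, 7 for TNF plus Senexin B against Senexin B and 0 for the interaction. The interaction had 4 called lists without replicate 1 of all groups, 1 without TNF replicate 1 and 4 without control replicate 2. Chemokine and cytokine genes were not called for TNF plus Senexin B against TNF without replicate 1 of all groups (camera adjusted p = 0.193).

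No label says that libraries with the same replicate number were paired. The 18 same-number correlations ran from -0.0123 to 0.103, and 1 was over 0.1, the bound set for pairing. Correlations between libraries of different groups and numbers ran from -0.0754 to 0.0462, so a weak pairing is not excluded. With a replicate block the counts were 1470, 479, 871, 827, 6 and 2026 in the order of TNF against control, Senexin B against control, TNF plus Senexin B against TNF and against Senexin B, interaction and mean TNF effect.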

Other observations

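Notch target genes, ribosomal protein genes and epithelial markers rose in TNF plus Senexin B against TNF under the preset correlation only. Of 10 Notch target genes, 2 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00324, and adjusted p = 0.0577 with an estimated correlation, 0.148 with GC-corrected offsets), with JAG1 at 0.62 ± 0.05 and HES4 at 0.49 ± 0.11. Of 59 cytosolic ribosomal protein genes, 8 rose and 0 fell, with 14 and 0 adjusted over the list alone (camera adjusted p = 0.000164, and adjusted p = 0.477 with an estimated correlation). Of 13 epithelial markers, 4 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00938, and adjusted p = 0.163 with an estimated correlation), with CLDN4 at 0.36 ± 0.05. That call was lost without TNF plus Senexin B replicate 3 (adjusted p = 0.0526) and with GC-corrected offsets (0.148). In TNF plus Senexin B against Senexin B, 2 epithelial markers rose and 1 fell, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.000378, and adjusted p = 0.0868 with an estimated correlation). There, 3 of 30 G2/M genes fell, also when adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.295 with an estimated correlation), a call lost without TNF plus Senexin B replicate 1 (0.0527).

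Some lists were called in no comparison. Of 24 HIF target genes, 2 rose and 5 fell with TNF (camera adjusted p = 0.538), 3 rose and 2 fell with Senexin B (0.840), and 2 rose and 1 fell in TNF plus Senexin B against TNF (0.855). Of 18 glycolysis genes, 2 fell with TNF (0.243), 1 fell with Senexin B (0.330) and 0 passed in TNF plus Senexin B against TNF (0.181). Of 16 NRF2 target genes, 3 rose and 1 fell with TNF (0.926), 2 rose and 2 fell with Senexin B (0.553), and 2 rose and 2 fell with Senexin B added to TNF (0.891). Of 26 core Mediator subunits, 0 passed with TNF (0.917) or Senexin B (0.553), and 1 fell with Senexin B added to TNF (0.855). Of 7 kinase module genes, 1 rose with TNF (0.407), 1 fell with Senexin B (0.402) and 1 rose with Senexin B added to TNF (0.698). Of 28 housekeeping genes, 2 rose with TNF (0.279), 1 rose and 2 fell with Senexin B (0.840), and 3 fell with Senexin B added to TNF (0.699). The 5 tested replication-dependent histone genes and 5 tested fibroblast markers gave 0 calls (camera adjusted p = 0.917, 0.235 and 0.263 for histones and 0.563, 0.514 and 0.606 for fibroblast markers in the same order). Blood cell markers held 137 counts in all libraries, and none was tested.

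Over 125 tests of a list in a comparison, 48 were called, and in 0 of these did the median or the mean log2 fold change have another sign than the test. Among the 77 not called, 18 had such a difference. For chemokine and cytokine genes with Senexin B, the test pointed up while the mean was -0.18 and the median 0.05 (camera adjusted p = 0.235). That mean takes in CCL20 at a fitted -1.86, from 1 count in control and 0 in Senexin B, so it cannot be read as a size.

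The first principal component held 33.3% of the variance, the second 13.04% and the third 8.88%. Ribosomal protein genes took from 5.499% to 5.991% of the counts.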
